A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

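The data are RNA-seq of budding yeast, 24 libraries from 4 strains at 0, 10 and 20 min in 0.4 M NaCl, with 2 libraries for each of 12 groups. Per the labels' protocols, the strains were made from W303-1a with sho1::HIS3 and a LEU2-marked reporter under the STL1 promoter at leu2, by replacing YPD1 with a cassette carrying TRP1 and HPH and SLN1 with one carrying URA3 and KanMX. Cells grew in synthetic complete medium to mid-log phase before salt. Total RNA was taken with the miRNeasy kit with DNase and made into TruSeq stranded mRNA libraries, per the labels' protocols. Per the labels, the authors used TopHat2 and Cuffdiff on genome build sacCer3 to make the FPKM values analysed here, 1 column per library. The versions, the annotation and any scaling between libraries are not given in the sources used here. Only these FPKM values were used, so no count or depth per library stands behind them, and the precision that depth gives is unknown.

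Columns were assigned to strain and time by their names, with strains 1, 2 and 3 of the columns taken as Mut1, Mut2 and Mut3. The columns end in 0 or 1, and which of the labels' replicates each stands for is not stated, so they are called library 0 and library 1. Of 7126 features, 6162 were matched to a locus tag or symbol of the R64 reference and 964 were kept under their own name. In all, 481 were listed at 0 in every library. Features with a mean of at least 1 FPKM over the 24 libraries were tested, 6359 in number, of which 5717 are protein-coding genes of the reference. Overlapping genes were taken from the reference coordinates (312 features, 189 of them tested). Near-identical copies were found with blastn 2.17.0 at 95% identity over 50% of the length (311 features, 110 of them tested). Named genes of these kinds are given as uncertain, ENA1 once for all its values.

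FPKM plus 1 was put on the log2 scale and fitted in limma 3.58.1 (R 4.3.3) as 12 group means over all 24 libraries, with moderated two-sided tests and a trend of the variance with the mean, on 12 residual degrees of freedom and a prior of 1.88. Adjusted p values are Benjamini and Hochberg values over the tested features of a comparison, and a gene is called at an adjusted p under 0.05. The comparisons are each time against the others within a strain, each mutant against the wild type and the mutants against each other at 0 min, and the difference between a mutant's and the wild type's change at 10 and at 20 min. Direct comparisons of mutants with the wild type in salt were added after the data were seen. Spreads given after a mean FPKM are SD over the libraries, and those after a log2 change are SE of the fit. Fold changes are taken from the log2 change of the fit, so they are ratios of FPKM plus 1. For genes of low FPKM they are smaller than the ratio of the mean FPKM values.

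The 30 gene lists, the panel, the comparisons, the thresholds and the first set of alternatives were fixed before the data were examined. The lists were tested with camera, with an inter-gene correlation preset at 0.01 and again with one estimated from the data, for lists of at least 3 tested members, adjusted over the lists of a comparison. Counts adjusted over the list alone use the Benjamini and Hochberg correction within the list. In all, 37 genes belong to more than 1 list. ARG5,6, MFALPHA1 and MFALPHA2 were not matched to a feature. For the test of salt-induced genes at 0 min, the set for each mutant holds genes that rose at least 2-fold at 10 min in the other mutants, so that the libraries of the mutant tested did not choose them.

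Named genes follow a rule fixed before the data were examined. It takes SLN1, YPD1, SHO1, HIS3, LEU2, TRP1, URA3 and the panel of STL1, GPD1, GPP1, GPP2, ENA1, GRE2, CTT1, HSP12, ALD3, HOG1, PBS2, SSK1, PTP2, PTP3, FUS1, PRM2, SLT2 and OCH1. It adds, for each comparison, up to 10 called genes that rose and 10 that fell with the largest log2 change, a mean of at least 5 FPKM and no overlap between the libraries of the groups. The overlap condition was not applied to response differences. It also adds, for each list, up to 4 called members with the largest absolute change. Members that moved against the direction of their list, and a few other list members, were named after their values were seen.

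The alternatives were a pseudocount of 0.1 FPKM, no filter, median-ratio rescaling of the columns, the library number as a block (over all strains or within each strain), a fit on the compared groups alone, an estimated correlation, and leaving out each library. Protein-coding genes alone, the block together with rescaling, and leaving out library 0 of Mut2 at 20 min in every comparison were added after the data were seen. The fit without the block was tested on simulated data for the comparison of Mut1 with the wild type at 0 min. In these data 100 genes were moved 2-fold and 100 others 4-fold. The moved genes all had a mean above 5 FPKM on the log2 scale, so the rates do not cover genes of lower FPKM. The fit without the block recovered 50% of 2-fold and 83% of 4-fold changes with 8 false calls. The fit with the block recovered 93% and 98% with 9 false calls. It was run on data simulated separately, with a library effect equal in all groups. The data for the fit without the block held no such shared effect. These figures therefore do not compare the fits, and the rate of false calls in the real libraries was not tested. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.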

Results

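RNA from budding yeast was sequenced in 24 libraries. They cover 4 strains, a wild type and 3 mutants called Mut1, Mut2 and Mut3, each kept for 0, 10 or 20 min in 0.4 M NaCl, with 2 libraries for each of the 12 groups. Sln1 is the histidine kinase that senses osmolarity, and Ypd1 is the protein that passes its phosphate on to the response regulators Ssk1 and Skn7. Falling phosphorylation of Ssk1 starts the Hog1 MAP kinase cascade. All strains derive from W303-1a, with SHO1, the sensor of the other branch of the pathway, replaced by HIS3 and a fluorescent reporter driven by the STL1 promoter placed at leu2 with a LEU2 marker. Mut1 carries Ypd1 M20D with Sln1 E1101K, E1110K and S1179D. Mut2 has the same Sln1 with Ypd1 M20D and M92K. Mut3 carries Ypd1 I13D with Sln1 E1101K, L1109K, E1110K and S1179D. The comparisons ask how the strains differ before salt, how each responds to salt, and whether the responses differ from that of the wild type.

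Values are FPKM for 7126 features, of which 6359 had a mean of at least 1 FPKM and were tested. Fold changes are ratios of FPKM plus 1, not of the mean FPKM values printed beside them. Read counts were not used here, so the depth behind each value is unknown. The FPKM sum per library ran from 1850836 to 2995688, and the 10 highest features held 16.6 to 31.1% of it. Between 638 and 735 features were listed at 0 in a library. Structural and other RNA genes summed to between 3933.6 and 14788.8 FPKM in 23 libraries and to 72599.1 in library 0 of Mut2 at 20 min, where 0 and 1 are the numbers in the column names. Libraries with the same number deviated from their group means in the same way: the correlation across genes of these deviations was 0.23 to 0.601 in all 66 pairs of groups. Counts from a fit with the library number as a block are therefore given beside the main counts, and every gene called without the block was also called with it. Fits that left out 1 library did not use the block and leave the library numbers unbalanced between groups. Calls lost in them can therefore reflect the library number as well as the strain or time. The labels do not state that the libraries of a group come from separate cultures, so each p measures only the spread between these libraries.

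The edited and marker genes were read first. SLN1 (YIL147C, chromosome IX, 69791 to 73453, build R64) stood at 22.3 ± 3.89 FPKM (SD, n = 2) in the untreated wild type, and YPD1 (YDL235C, chromosome IV, 33415 to 33918) at 84.1 FPKM. Neither was called between any mutant and the wild type at 0 min. SHO1 (YER118C, chromosome V, 397952 to 399055) was listed at 0 in all 24 libraries. HIS3 (YOR202W), URA3 (YEL021W) and TRP1 (YDR007W) were not called between any mutant and the wild type at 0 min. TRP1, the marker of the YPD1 cassette, went from 129 FPKM in the wild type to 187 in Mut1 (adjusted p = 0.0955), and with the block it was called in Mut1 (adjusted p = 0.000151), Mut2 (0.000197) and Mut3 (5.63e-05). LEU2 (YCL018W, chromosome III, 91324 to 92418) rose in salt in all 4 strains. In the wild type it went from 353 ± 30.2 to 943 ± 58.6 FPKM at 10 min, a log2 change of 1.41 ± 0.18 (SE) or 2.67-fold (adjusted p = 2.07e-05). The 10 min rise was 3.05-fold in Mut1, 2.86-fold in Mut2 and 2.51-fold in Mut3.

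Salt strongly raised the osmostress genes of the wild type within 10 min. STL1 (YDR536W, chromosome IV, 1508005 to 1509714), which encodes the glycerol importer, went from 5.77 ± 0.0114 to 2560 ± 39.5 FPKM (378-fold, adjusted p = 3.98e-16). The genes of glycerol synthesis rose with it: GPD1 (YDL022W, chromosome IV, 411825 to 413000) from 129 ± 1.87 to 9230 ± 502 FPKM (70.8-fold, adjusted p = 2.84e-13), GPP2 58.7-fold, and GPP1 (YIL053W, chromosome IX, 255115 to 255867) 2.85-fold. ENA1 (YDR040C, chromosome IV, 535192 to 538467), the sodium pump gene, rose 31.5-fold to 131 ± 2.36 FPKM, a value that its near-identical copies ENA2 and ENA5 make uncertain, as they do all ENA1 values below. The reductase gene GRE2 rose 44.3-fold, the catalase gene CTT1 386-fold, the membrane protein gene HSP12 384-fold and the aldehyde dehydrogenase gene ALD3 158-fold. Of the pathway's own genes, SSK1 rose 3.65-fold and the phosphatase genes PTP2 and PTP3 rose 2.56-fold and 1.43-fold, whereas HOG1 and PBS2 were not called. SLN1 fell 1.32-fold (adjusted p = 0.0431), a call lost without WT 0 min library 1 (adjusted p = 0.319), WT 10 min library 0 (0.234) or WT 10 min library 1 (0.051). YPD1 fell to 51.2 ± 4.43 FPKM and was called only with the block (adjusted p = 0.0652 without, 0.00573 with). FUS1 (YCL027W, chromosome III, 71803 to 73341), a pheromone-response gene, rose 1.69-fold (adjusted p = 0.0131). OCH1 (YGL038C, chromosome VII, 425362 to 426804), a mannosyltransferase gene controlled by Skn7, rose 1.61-fold. These calls were lost without WT 0 min library 0 (adjusted p = 0.124 for FUS1 and 0.104 for OCH1) or WT 10 min library 1 (0.131 and 0.0794). PRM2, SLT2, HIS3, TRP1 and URA3 were not called. With the block HOG1 (adjusted p = 0.00119), PRM2 (0.0272) and SLT2 (2.05e-05) were called as higher.

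Outside that panel, the largest rises at 10 min in the wild type were those of RTC3 (426-fold), the stress gene DDR2 (257-fold), FMP48 (161-fold), PHM7 (151-fold) and FMP45 (128-fold). The largest falls included RFU1 (13.9-fold), RRN11, which encodes an RNA polymerase I factor (10.6-fold), BSC1 (10.3-fold), the ribosomal protein chaperone gene SYO1 (9.67-fold) and SFG1 (9.03-fold). In all, 2239 genes changed with adjusted p under 0.05, 1117 up and 1122 down, and 1177 of them by at least 2-fold. The block gave 3918, 2022 up and 1896 down.

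The fixed gene lists separate the rising from the falling functions. Of 28 osmostress-induced Hog1 targets, 26 rose and AQR1 fell (27 and 1 adjusted over the list alone), with a median log2 change of 4.68 (camera adjusted p = 1.11e-25, and adjusted p = 0.00168 with an estimated correlation). Of 41 general stress genes driven by Msn2 and Msn4, 39 rose (40 adjusted over the list alone; adjusted p = 1.71e-27, but adjusted p = 0.063 with an estimated correlation). Of 21 trehalose and glycogen genes, 18 rose (also 18 adjusted over the list alone; adjusted p = 5.1e-12, but adjusted p = 0.128 with an estimated correlation), among them TSL1 (51.5-fold) and TPS2 (32.7-fold). Chaperone genes controlled by Hsf1 rose in 19 of 25 cases (20 adjusted over the list alone; adjusted p = 1.3e-10, but adjusted p = 0.0614 with an estimated correlation), with HSP42 up 106-fold, HSP26 22.1-fold and HSP104 21-fold. Of 14 glycerol genes 7 rose (7 adjusted over the list alone; adjusted p = 9.39e-06, but adjusted p = 0.106 with an estimated correlation). Of 24 autophagy genes 14 rose, ATG8 4.73-fold, and ATG41 fell (14 and 1 adjusted over the list alone; adjusted p = 2.33e-06, but adjusted p = 0.106 with an estimated correlation). In the calcineurin and ion list of 26 genes, 12 rose, including CMK2 (20-fold), and TRK1 and PMA1 fell (14 and 2 adjusted over the list alone; adjusted p = 0.00017, but adjusted p = 0.393 with an estimated correlation).

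Falls were most frequent among genes of ribosome biogenesis. Of 114 ribosome biogenesis genes, 104 fell and 0 rose (108 and 0 adjusted over the list alone), with a median log2 change of -1.77 (adjusted p = 1.48e-35, but adjusted p = 0.0878 with an estimated correlation). UTP6 fell 8.6-fold and RRP12 6.8-fold. Of 139 ribosomal protein genes 16 fell at 10 min, RPL22B 4.22-fold among them (12 adjusted over the list alone; adjusted p = 0.00264, and adjusted p = 0.788 with an estimated correlation). Of 42 amino acid genes under Gcn4, 24 fell, including ILV5 (3.21-fold) and ASN1 (2.53-fold), and HIS5 and SER3 rose, the latter with a value that its overlap with SRG1 makes uncertain (26 and 2 adjusted over the list alone; adjusted p = 2.33e-06, but adjusted p = 0.0844 with an estimated correlation). Members of the cell cycle lists fell as well. In the G2/M list 10 of 18 fell, such as the cyclin gene CLB2 (4.24-fold), and MOB1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.000687, but adjusted p = 0.331 with an estimated correlation). In the G1/S list 11 of 32 fell and PCL1 rose (11 and 1 adjusted over the list alone; adjusted p = 0.0101, but adjusted p = 0.399 with an estimated correlation), and in the M/G1 list 7 of 20 fell and PIR1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.0281, but adjusted p = 0.602 with an estimated correlation).

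Smaller shifts were called in 5 further lists, each lost with an estimated correlation. Mitochondrial respiration had 15 of 49 up, led by CYC7 (37.2-fold), and 2 down, ATP20 and NDE1 (15 and 2 adjusted over the list alone; adjusted p = 0.00171, and adjusted p = 0.106 with an estimated correlation). The proteasome list had 10 of 34 up, with its activator gene RPN4 up 4.54-fold (9 adjusted over the list alone; adjusted p = 0.00299, and adjusted p = 0.399 with an estimated correlation). The oxidative stress list had 8 of 24 up and YCF1 down (8 and 1 adjusted over the list alone; adjusted p = 0.0153, and adjusted p = 0.602 with an estimated correlation). Glycolysis had 6 of 24 up, with GLK1 up 46.9-fold although it overlaps YCL042W, and ADH2 and PFK2 down (6 and 2 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.406 with an estimated correlation). Meiotic and sporulation genes, listed as a marker of another cell type, had 12 of 28 up, including IME2 (3.8-fold), and 2 down (13 and 2 adjusted over the list alone; adjusted p = 0.00264, and adjusted p = 0.138 with an estimated correlation).

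The remaining lists were not shifted as a whole at 10 min in the wild type, although members moved. The mating list had 7 of 27 up and 6 down, among them the receptor gene STE2 (4.5-fold lower) (7 and 7 adjusted over the list alone; adjusted p = 0.947). The cell wall list had 8 of 27 up and 3 down (8 and 3 adjusted over the list alone; adjusted p = 0.139), the filamentous growth list 2 of 14 up and 3 down (2 and 4 adjusted over the list alone; adjusted p = 0.43), the pathway components 6 of 23 up, with MSN2 up 5.01-fold, and 2 down (6 and 2 adjusted over the list alone; adjusted p = 0.442), and the phosphatases 4 of 10 up (4 adjusted over the list alone; adjusted p = 0.0531). Hexose transport had 4 of 16 up, led by HXT5 (47.8-fold), and 3 down, HXT3 (3.75-fold), HXT2 (2.59-fold) and MIG1 (4 and 5 adjusted over the list alone; adjusted p = 0.811). The iron list had 4 of 24 up and 8 down (4 and 8 adjusted over the list alone; adjusted p = 0.441), phosphate starvation 1 of 17 up and 3 down, with PHO84 7.97-fold lower, a gene that overlaps the RNA gene YNCM0001W (1 and 3 adjusted over the list alone; adjusted p = 0.144), methionine 1 of 24 up and 4 down (1 and 4 adjusted over the list alone; adjusted p = 0.811), and ergosterol 5 of 26 up and 2 down (5 and 2 adjusted over the list alone; adjusted p = 0.918). None of 9 histone genes was called by limma (0 adjusted over the list alone; adjusted p = 0.797 for the list). Of the 4 genes specific to the other mating type in the table, 2 were tested and 0 were called.

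At 20 min the wild type was again compared with 0 min. STL1 stood at 3050 ± 60.3 FPKM, 451-fold above 0 min, HSP12 at 42300 ± 14800 (729-fold), CTT1 at 4650 (583-fold) and ALD3 at 1910 (377-fold). GPD1 was 76.4-fold, GPP2 80.7-fold, GRE2 70.6-fold and ENA1 24.7-fold above 0 min. YPD1 was 2.08-fold lower (adjusted p = 0.00649, and 0.089 without WT 20 min library 1). In ribosome biogenesis 113 of 114 genes were down (113 adjusted over the list alone) with RRP12 28.8-fold, UTP23 24.7-fold and NSR1 20.1-fold lower. The hexose transporter genes HXT2 and HXT3 were 16.9-fold and 11-fold lower and STE2 7.67-fold lower. Of the 139 ribosomal protein genes 110 were now down (116 adjusted over the list alone; adjusted p = 4.62e-16, but adjusted p = 0.363 with an estimated correlation). All 41 general stress genes were up (41 adjusted over the list alone), as were 19 of 24 autophagy genes, with ATG8 9.4-fold higher. In total 2987 genes differed from 0 min, 1555 up and 1432 down (4494 with the block, 2467 up and 2027 down).

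Between 10 and 20 min in the wild type, some salt-induced genes rose further. DAK1, for the breakdown of dihydroxyacetone (2.51-fold), ALD3 (2.38-fold, adjusted p = 0.00412) and ATG8 (1.99-fold) rose, and GPP2 rose 1.37-fold (adjusted p = 0.0394). The sugar transporter genes HXT2 (6.53-fold), HXT4 (4.37-fold) and HXT3 (2.95-fold) fell. So did the ribosome biogenesis genes NSR1 (5.71-fold), UTP23 (4.98-fold), DBP2 (4.57-fold) and NOG1 (4.27-fold). Other genes that had risen by 10 min fell, namely the meiotic kinase gene IME2 (2.08-fold), the calmodulin kinase gene CMK2 (1.82-fold) and RPN4 (1.7-fold). STL1, GPD1, ENA1, GRE2, CTT1 and HSP12 were not called. With the block STL1 (adjusted p = 0.0147), GRE2 (0.000232), CTT1 (0.00151) and HSP12 (0.00012) were called as higher at 20 min, and ENA1 (0.0313) as lower. On rescaling GRE2 (0.0136) and CTT1 (0.0253) were called as higher. The ribosomal protein genes RPL22A (16.9-fold), RPL43A (13.6-fold) and RPL36B (7.97-fold) were higher at 20 min while 72 other members of their list fell, but they also differ between sets of libraries that coincide with these times, so these rises are uncertain. The call of ALD3 was lost without WT 20 min library 1 (adjusted p = 0.0511). That of GPP2 was lost without WT 10 min library 0 (0.151) or library 1 (0.135), or without WT 20 min library 0 (0.0925) or library 1 (0.223). In all 904 genes changed, 390 up and 514 down (2658 with the block, 1449 up and 1209 down). Leaving out 1 library left 498 (WT 10 min library 0), 522 (WT 10 min library 1), 509 (WT 20 min library 0) or 430 (WT 20 min library 1), and a fit on the compared groups alone called 0.

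**Figure D1:**
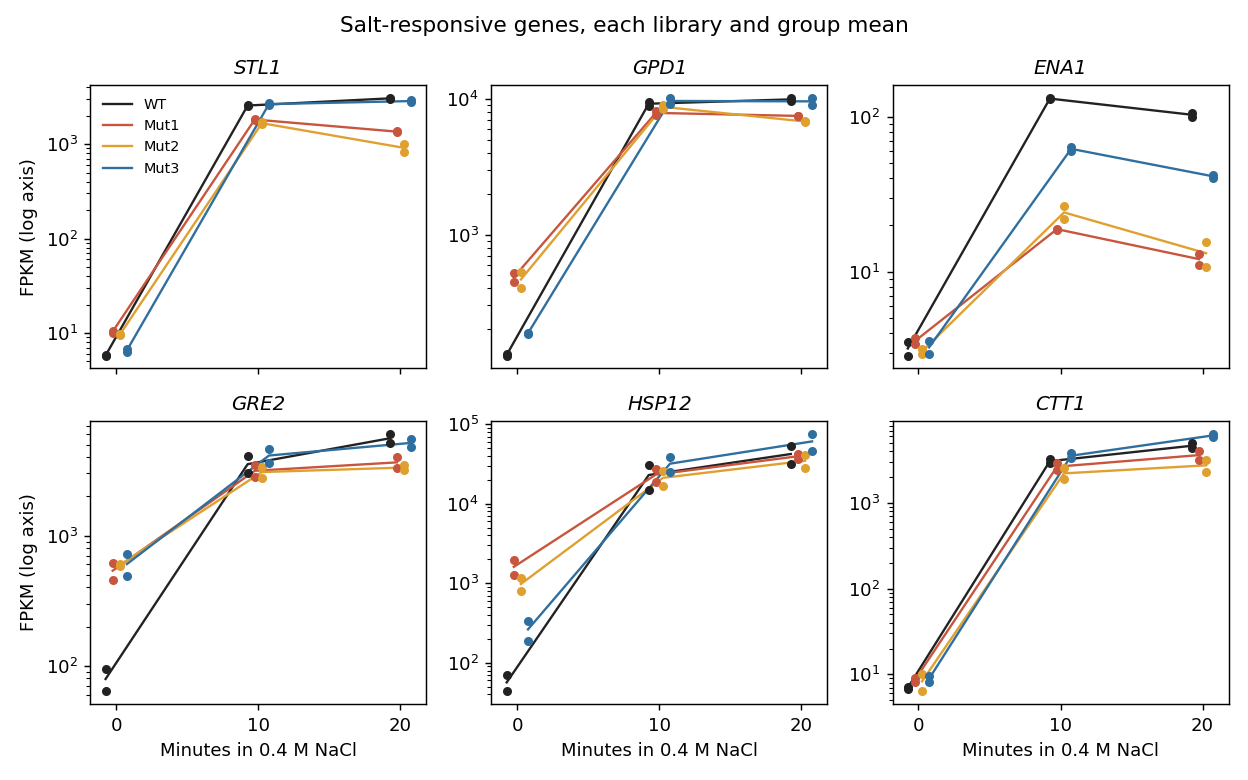
FPKM of panel genes on a log axis against minutes in 0.4 M NaCl for the 4 strains. Points are single libraries and lines join the group means; STL1 reached 3050 FPKM at 20 min in the wild type, 1360 in Mut1, 915 in Mut2 and 2850 in Mut3.

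The mutants also induced the osmostress genes in salt. At 10 min STL1 rose 161-fold in Mut1 (from 10.3 to 1820 FPKM), 158-fold in Mut2 (from 9.59 to 1670) and 351-fold in Mut3 (from 6.55 to 2650 ± 112). GPD1 rose 16.3-fold, 18.9-fold and 51.4-fold, and GPP2 rose 16.2-fold, 17.3-fold and 42.2-fold, in that order. ENA1 rose 4.35-fold to 18.8 ± 0.145 FPKM in Mut1, 6.15-fold to 24.1 ± 3.38 in Mut2 and 14.8-fold to 61.9 ± 2.54 in Mut3, values that ENA2 and ENA5 make uncertain. CTT1 rose 275-fold, 242-fold and 360-fold, ALD3 171-fold, 175-fold and 239-fold, HSP12 14.5-fold, 21.5-fold and 123-fold, and GRE2 5.88-fold, 5.14-fold and 6.88-fold. SSK1 rose 1.97-fold in Mut1 and 3.76-fold in Mut3. In Mut2 it rose 1.89-fold, a call lost without Mut2 0 min library 0 (adjusted p = 0.0572) or Mut2 10 min library 1 (0.0703). SLN1 fell 1.35-fold in Mut2, a call lost without Mut2 0 min library 0 (0.0845) or library 1 (0.115) or Mut2 10 min library 0 (0.144) or library 1 (0.0678). In Mut3 SLN1 fell 1.45-fold, a call lost without Mut3 0 min library 1 (0.0886) or Mut3 10 min library 0 (0.0735). FUS1 rose 2.02-fold in Mut1 and 2.92-fold in Mut3. PTP2 rose in Mut3 (2.99-fold) and was not called in Mut1 or Mut2. Among other genes, FMP45 rose 110-fold in Mut1, and TOD6 (21.2-fold), DHR2 (13.4-fold) and FRE1 (10.9-fold) fell there. Of the 28 Hog1 targets 26 rose in Mut1, 26 in Mut2 and 27 in Mut3, with AQR1 down in each (26, 26 and 27 adjusted over the list alone; adjusted p = 0.00276, 0.00265 and 0.00156 with an estimated correlation). Of 114 ribosome biogenesis genes 111, 107 and 107 fell (111, 111 and 112 adjusted over the list alone). In Mut1 1991 genes changed at 10 min, 1006 up and 985 down (3697 with the block, 1998 up and 1699 down). In Mut2 2012 changed, 1035 up and 977 down (3741 with the block, 1997 up and 1744 down), and in Mut3 2176, 1113 up and 1063 down (3851 with the block, 2060 up and 1791 down).

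At 20 min STL1 was 120-fold above 0 min in Mut1 (1360 ± 35.8 FPKM), 86-fold in Mut2 (915 ± 141) and 378-fold in Mut3 (2850). ENA1 was 2.85-fold, 3.42-fold and 9.93-fold higher. GPD1 was 15.5-fold, 14.7-fold and 51-fold, CTT1 374-fold, 299-fold and 622-fold, and ALD3 331-fold, 285-fold and 566-fold above 0 min. All 41 general stress genes were up in Mut1 and Mut3 and 39 in Mut2 (41, 41 and 39 adjusted over the list alone). Ribosomal protein genes fell in 97, 102 and 115 of 139 cases in Mut1, Mut2 and Mut3 (116, 122 and 120 adjusted over the list alone). In total 2526 genes changed in Mut1, 1284 up and 1242 down (4041 with the block, 2159 up and 1882 down), 2529 in Mut2, 1369 up and 1160 down (4109 with the block, 2258 up and 1851 down), and 3032 in Mut3, 1607 up and 1425 down. The block gave 4478, 2509 up and 1969 down in Mut3. Rescaling the libraries to equal median ratios moved the median change of all genes most in this last comparison, from 0.1 to 0 on the log2 scale.

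Between 10 and 20 min STL1 fell in Mut2 (1.83-fold, adjusted p = 0.000618). ENA1 fell in Mut2 too (1.8-fold, adjusted p = 0.00721), a call lost without Mut2 10 min library 1 (adjusted p = 0.052) or Mut2 20 min library 0 (0.0615). In Mut3 ALD3 rose 2.37-fold (adjusted p = 0.00397, and 0.0541 without Mut3 10 min library 0), NSR1 fell 9.11-fold, DBP2 6.57-fold and HXT2 6.42-fold. HXT2 fell also in Mut1 (2.9-fold) and Mut2 (3.15-fold). In Mut1 STL1 fell 1.34-fold (adjusted p = 0.0489), a call lost on rescaling (0.375) and without Mut1 10 min library 0 (0.233) or library 1 (0.252) or Mut1 20 min library 0 (0.2) or library 1 (0.207). In Mut1 191 genes changed, 88 up and 103 down (1290 with the block, 651 up and 639 down). After rescaling the share that rose was 59.7% instead of 46.1%. Leaving out 1 library left 44 (Mut1 10 min library 0), 59 (Mut1 10 min library 1), 109 (Mut1 20 min library 0) or 32 (Mut1 20 min library 1), and a fit on the compared groups alone called 5. In Mut2 274 changed, 136 up and 138 down (1803 with the block, 934 up and 869 down), with 34 left without Mut2 10 min library 0 and 148 without Mut2 20 min library 0. In Mut3 902 changed, 393 up and 509 down (2693 with the block, 1541 up and 1152 down), with 406 left without Mut3 10 min library 0, 590 without library 1, 533 without Mut3 20 min library 0 and 503 without library 1. A fit on the compared groups alone called 0 genes in Mut2 and 0 in Mut3.

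Before salt, Mut1 already expressed part of the salt programme. HSP12 stood at 1610 ± 484 FPKM against 56.7 ± 18.3 in the wild type (28-fold, adjusted p = 1.27e-05), DDR2 at 1390 (35.6-fold) and GPD1 at 484 ± 54 against 129 ± 1.87 (3.71-fold, adjusted p = 1.22e-06). GRE2 was 6.76-fold, GPP2 2.88-fold and STL1 1.67-fold higher, the last at 10.3 ± 0.327 FPKM (adjusted p = 0.000493). PTP2 was 2.13-fold and PTP3 1.63-fold higher, and OCH1 stood at 158 FPKM (2.72-fold higher). ENA1, CTT1 and ALD3 were not called, and ALD3 was with the block (adjusted p = 0.8 without, 0.042 with). SLT2 stood at 97.1 and 319 FPKM in libraries 0 and 1 of Mut1, against 31.1 and 114 in the wild type. The cell wall protein gene PIR3 went from 48.5 to 1210 ± 138 FPKM (25-fold, adjusted p = 8.02e-09), with PUN1 (3.7-fold) and CIS3 (3.1-fold). NFG1 (15.3-fold), IMD2 (9.51-fold), DDR48 (8.36-fold) and PRY2 (7.28-fold) were also higher. So were the oxidative stress genes SRX1 (7.18-fold), OYE3 (4.88-fold) and GTT2 (4.12-fold), the sulfate assimilation genes MET16 (3.98-fold) and MET3 (3.63-fold), and the autophagy gene ATG8 (2.87-fold). Lower were PHO84, the phosphate transporter gene that overlaps YNCM0001W (8.3-fold), the endonuclease gene HO (5.96-fold), BSC1 (5.85-fold), the permease gene DIP5 (3.77-fold), the amino acid genes ARG3 (3.76-fold) and HIS4 (2.35-fold), and the mating genes MFA1 (3.45-fold), BAR1 (3.42-fold) and SST2 (3.38-fold). FUS1 was 2.17-fold lower (adjusted p = 0.00556), a call lost without WT 0 min library 1 (adjusted p = 0.0813) or Mut1 0 min library 0 (0.0665).

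By list, 11 of the 28 Hog1 targets were higher in Mut1 before salt and AQR1 was lower (12 and 1 adjusted over the list alone; adjusted p = 1.15e-13, and adjusted p = 0.00965 with an estimated correlation). Of 24 oxidative stress genes 11 were higher (16 adjusted over the list alone; adjusted p = 6.47e-19, and adjusted p = 0.0485 with an estimated correlation), and of 27 cell wall genes 9 (17 adjusted over the list alone; adjusted p = 8.53e-17, and 0.0424 with an estimated correlation). Of 42 amino acid genes 13 were lower and LEU4 was higher (22 and 1 adjusted over the list alone; adjusted p = 6.09e-19, and 0.00195 with an estimated correlation). Of 49 respiration genes 8 were higher, among them SDH4 (1.77-fold) (22 adjusted over the list alone; adjusted p = 3.99e-15, and 0.00195 with an estimated correlation). With the block and an estimated correlation together, camera kept the calls of oxidative stress (adjusted p = 0.0345) and respiration (0.0407). It lost those of the Hog1 targets (0.0557), cell wall genes (0.0641) and amino acid genes (0.0623). Of 27 mating genes 7 were lower and 3, among them PRM5 and PRM10, the latter uncertain through its overlap with YJL107C, were higher (9 and 3 adjusted over the list alone; adjusted p = 1.57e-05, but adjusted p = 0.0797 with an estimated correlation). In total 294 genes differed between Mut1 and the wild type at 0 min, 195 higher and 99 lower (1148 with the block, 735 up and 413 down). Leaving out 1 library left 176 (WT 0 min library 0), 181 (Mut1 0 min library 0) or 185 (Mut1 0 min library 1). A fit on the compared groups alone, which has fewer samples, called 0 genes here.

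Mut2 carried a similar set before salt. HSP12 stood at 978 ± 252 FPKM (17.1-fold above the wild type), GPD1 at 466 ± 91.7 (3.55-fold), GRE2 at 595 (7.57-fold), GPP2 at 314 (2.8-fold) and PIR3 at 1210 ± 84.5 (25-fold). STL1 was 1.56-fold higher at 9.59 FPKM (adjusted p = 0.0017, and 0.0759 after rescaling). DDR2 was 28.4-fold, SRX1 9.31-fold, PRY2 7.48-fold, DDR48 7.19-fold, OYE3 5.51-fold, GTT2 4.93-fold, PTP2 2.4-fold and OCH1 2.83-fold higher, the last at 165 FPKM. The cell wall genes CIS3 (3.87-fold), PUN1 (3.55-fold) and PIR1 (2.07-fold), the sulfate genes MET16 (3.54-fold) and MET3 (3.14-fold) and the iron-sulfur scaffold gene ISU2 (2.91-fold) were higher as well. COX26 was 8.55-fold, BSC1 6.02-fold, SST2 4.2-fold, HO 3.81-fold, ARG3 3.35-fold, STE2 3.34-fold and BAR1 2.94-fold lower. FUS1 was called only with the block (adjusted p = 0.095 without, 0.00343 with). SLT2 stood at 106 and 323 FPKM in libraries 0 and 1 of Mut2, against 31.1 and 114 in the wild type. Of the 28 Hog1 targets 10 were higher and AQR1 lower (11 and 1 adjusted over the list alone; adjusted p = 4.65e-12, and 0.0424 with an estimated correlation), and of 24 oxidative stress genes 15 were higher (17 adjusted over the list alone; adjusted p = 3.8e-22, and 0.0424 with an estimated correlation). Of 27 cell wall genes 11 were higher (16 adjusted over the list alone; adjusted p = 7.12e-19, and 0.0424 with an estimated correlation). Camera with the block and an estimated correlation together kept the call of oxidative stress (adjusted p = 0.0254). It lost those of the Hog1 targets and cell wall genes (0.0911 each). In total 287 genes differed, 184 higher and 103 lower (1326 with the block, 774 up and 552 down), with 169 left without WT 0 min library 0 and 173 without Mut2 0 min library 1. On the compared groups alone 0 were called.

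In Mut3 fewer genes were called against the wild type before salt, and oxidative stress genes were among them. GRE2 stood at 605 ± 163 FPKM (7.55-fold higher, adjusted p = 8.01e-06), and GTT2 was 9.7-fold, OYE3 7.52-fold, AAD4 7.43-fold and YML131W 5.61-fold higher. DDR2 (21.6-fold), DDR48 (6.87-fold), the glyceraldehyde phosphate dehydrogenase gene TDH1 (5.59-fold), MET16 (3.68-fold), MET3 (3.42-fold), ISU2 (2.99-fold), PIR3 (2.39-fold), OCH1 (2.27-fold, at 132 FPKM) and RPN4 (1.9-fold) were higher. STL1 was not called (adjusted p = 1), nor was PTP2 (0.391), and GPD1 only with the block (0.0777 without, 0.00914 with). HSP12 was 4.51-fold higher at 264 ± 108 FPKM (adjusted p = 0.0195). The call was lost on rescaling (0.0956) and without WT 0 min library 1 or Mut3 0 min library 0. With the block it was kept (adjusted p = 1.81e-07), and the log2 difference was 2.27 within library 0 and 2.07 within library 1. GPP2 was 1.53-fold higher (adjusted p = 0.0364), a call lost without any 1 of the WT or Mut3 libraries at 0 min. With the block it was kept (adjusted p = 0.000104), with 0.63 within library 0 and 0.59 within library 1. TOM7 (3.72-fold), FRE4 (3.06-fold), ARG3 (2.87-fold) and OPT2 (2.43-fold) were lower. Of 24 oxidative stress genes 18 were higher (18 adjusted over the list alone; adjusted p = 1.13e-46, and 0.00507 with an estimated correlation). Of the 28 Hog1 targets 5 were higher (6 up and 2 down adjusted over the list alone; adjusted p = 9.98e-08, and 0.0489 with an estimated correlation). Camera with the block and an estimated correlation together kept the call of oxidative stress (adjusted p = 0.00155) and lost that of the Hog1 targets (0.127). In total 103 genes differed, 76 higher and 27 lower (503 with the block, 337 up and 166 down). The compared groups alone gave 0.

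Genes that rose at least 2-fold at 10 min in the other 2 mutants were then compared with the wild type at 0 min as a set. In Mut1, 59 of 430 such genes were higher and 5 lower (153 and 14 with the block), with a median log2 difference of 0.26 (camera p = 1.2e-14, but p = 0.134 with an estimated correlation). That median was 0.13 and 0.41 without WT 0 min library 0 and library 1, and 0.40 and 0.13 without Mut1 0 min library 0 and library 1. In Mut2, 50 of 434 were higher and 5 lower (141 and 23 with the block), with a median of 0.2 (p = 6.9e-12, and p = 0.185 with an estimated correlation). Without the same wild type libraries it was 0.07 and 0.34, and without those of Mut2 0.43 and 0. In Mut3, 23 of 456 were higher and 1 lower (109 and 4 with the block), with a median of 0.21 (p = 3.43e-16, and p = 0.114 with an estimated correlation). Without the wild type libraries it was 0.05 and 0.35, and without those of Mut3 0.33 and 0.06.

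**Figure D2:**
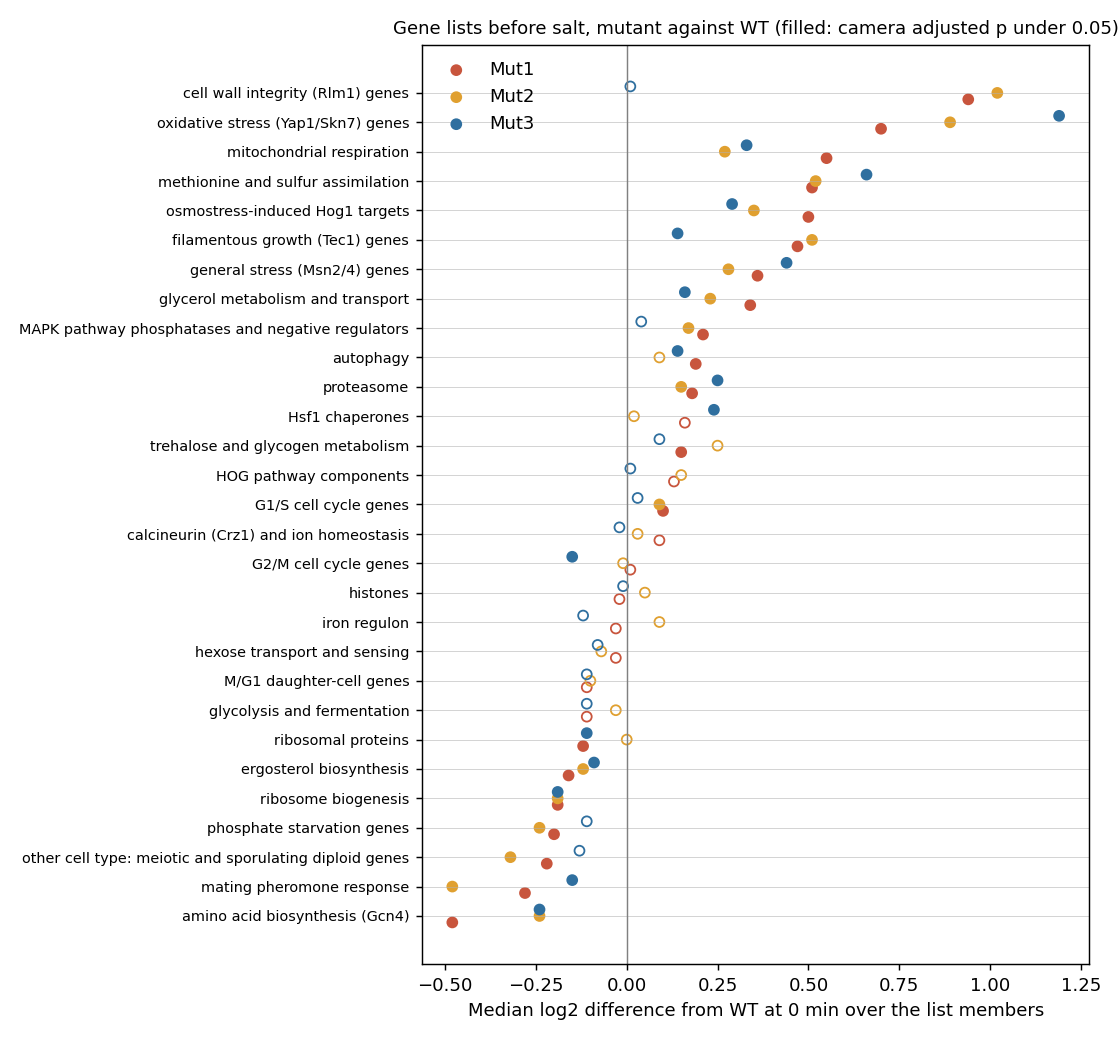
Median log2 difference from the wild type at 0 min (horizontal axis) of the gene lists (vertical axis) in Mut1, Mut2 and Mut3, one point per list and strain. Oxidative stress genes had medians of 0.7, 0.89 and 1.19, and cell wall genes 0.94 in Mut1 and 1.02 in Mut2.

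The mutants were compared with each other before salt. Mut2, which adds Ypd1 M92K to Mut1, differed from Mut1 in 0 genes by limma (106 at an unadjusted p under 0.05, and 1 with the block). The difference was -0.10 for STL1 (95% interval -0.33 to 0.13), -0.06 for GPD1 (-0.35 to 0.23), -0.71 for HSP12 (-1.67 to 0.25) and 0.17 for PTP2 (-0.16 to 0.49), in log2 units. As lists, amino acid genes were higher in Mut2 (5 adjusted over the list alone; adjusted p = 1.48e-22, and 0.000988 with an estimated correlation) and respiration genes lower (adjusted p = 6.56e-15, and 0.000988 with an estimated correlation). Both list calls were lost in camera with the block and an estimated correlation together (adjusted p = 0.0708 each). Leaving out Mut1 0 min library 0 or library 1 gave 1 and 2 genes. Mut3 had lower levels than Mut1 of PIR3 (10.4-fold), PTP2 (2.83-fold, adjusted p = 9.9e-05), GPD1 (2.57-fold, adjusted p = 9.17e-05) and GPP2 (1.88-fold, adjusted p = 0.00224), and higher levels of HO (4.12-fold), GAP1 (3.52-fold) and HIS4 (2.41-fold). HSP12 was 6.22-fold lower (adjusted p = 0.00564), a call lost without Mut1 0 min library 0 or Mut3 0 min library 1. With the block it was kept (adjusted p = 1.39e-07), and the log2 difference was -2.52 within library 0 and -2.76 within library 1. SLT2 was called as lower only with the block (adjusted p = 0.000845). STL1 was 1.5-fold lower (adjusted p = 0.00935), a call lost on rescaling (0.244) and without Mut1 0 min library 0 (0.0887) or library 1 (0.0592) or Mut3 0 min library 1 (0.0947). Of the 27 cell wall genes 8 were lower (16 adjusted over the list alone; adjusted p = 5.3e-22, but adjusted p = 0.0623 with an estimated correlation). In total 114 genes differed, 38 higher and 76 lower in Mut3 (563 with the block, 208 up and 355 down), and 59, 50, 52 or 66 without Mut1 0 min library 0, Mut1 0 min library 1, Mut3 0 min library 0 or Mut3 0 min library 1. The compared groups alone gave 6. Against Mut2, Mut3 had lower PIR3 (10.5-fold), PTP2 (3.18-fold) and GPD1 (2.46-fold) and higher SST2 and HO (2.63-fold each). SLT2 was called as lower only with the block (adjusted p = 0.000464). Of the cell wall genes 9 were lower (17 adjusted over the list alone; adjusted p = 2.22e-25, and 0.0369 with an estimated correlation). That list call was lost in camera with the block and an estimated correlation together (adjusted p = 0.109). In total 120 genes differed, 36 higher and 84 lower (644 with the block, 245 up and 399 down), and 74, 45, 35 or 73 without Mut2 0 min library 0, Mut2 0 min library 1, Mut3 0 min library 0 or Mut3 0 min library 1. The compared groups alone gave 2.

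The salt response itself differed between mutants and the wild type, tested as the difference of the log2 changes. In Mut1 at 10 min the response of HSP12 was smaller by a log2 value of -4.73 ± 0.63 (SE), that of DDR2 by -4.36, of GRE2 by -2.92, of ENA1 by -2.86 ± 0.22 (adjusted p = 7.01e-06), of GPD1 by -2.12, of GPP2 by -1.86 and of STL1 by -1.23 (adjusted p = 0.000382). PTP2 and the kinase gene RCK1 followed, at -1.23 and -2.15, with RPN4 at -1.42, the decarboxylase gene PDC6 at -2.51 and IME2 at -1.71. CTT1 and ALD3 were not called. The response of SLT2 was called as smaller only with the block, at -1.35 at 10 min (adjusted p = 0.00344) and -2.03 at 20 min (0.000162). The responses of BSC1 (3.14), PRM7 (3.11), PHO84 (2.42, with the overlap given above) and the methionine synthase gene MET6 (2.14) lay above those of the wild type. Of the 28 Hog1 targets 10 had smaller responses (13 adjusted over the list alone; adjusted p = 4.16e-13, and 0.0278 with an estimated correlation). In total 165 responses differed, 57 above and 108 below the wild type (1042 with the block, 471 up and 571 down). Leaving out 1 library left 79 (WT 0 min library 0), 103 (WT 10 min library 0), 85 (WT 10 min library 1), 92 (Mut1 0 min library 0 or library 1) or 81 (Mut1 10 min library 0 or library 1), and the compared groups alone gave 7. At 20 min the values were -4.86 for HSP12, -3.37 for GRE2, -3.12 for ENA1 (adjusted p = 2.27e-06), -2.30 for GPD1, -2.15 for GPP2, -1.91 for STL1 and -2.29 for PUN1. The responses of PHO84 (3.43), BSC1 (3.36), MET6 (2.52) and STE2 (2.16) lay above. Of the Hog1 targets 12 had smaller responses (13 adjusted over the list alone; adjusted p = 2.16e-17, and 0.00883 with an estimated correlation). In total 159 differed, 56 above and 103 below (984 with the block, 421 up and 563 down), and 103 and 105 without Mut1 0 min library 0 and library 1, 88 without WT 20 min library 1 and 99 without Mut1 20 min library 0. The compared groups alone gave 23.

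In Mut2 the same panel genes had smaller responses, that of SLT2 at 10 min only with the block (-1.50, adjusted p = 0.00178). At 10 min the differences were -4.16 for HSP12, -4.18 for DDR2, -3.11 for GRE2, -2.36 for ENA1, -1.91 for GPD1, -1.76 for GPP2 and -1.26 for STL1. At 20 min they were -4.36 for HSP12, -3.66 for GRE2, -3.53 for SRX1, -2.85 for ENA1, -2.37 for GPD1 and GPP2, and -2.39 for STL1 (adjusted p = 8.52e-07). BSC1 lay above the wild type at 10 min (3.29). RPL43A (4.50) and RPL22A (4.23) did so too, but the sets of libraries named above coincide with this comparison, so they are uncertain. Of the 28 Hog1 targets 9 had smaller responses at 10 min (13 down and 1 up adjusted over the list alone; adjusted p = 1.4e-13, and 0.0242 with an estimated correlation). At 20 min 12 did and GCY1 went the other way (16 and 1 adjusted over the list alone; adjusted p = 2.71e-20, and 0.00452 with an estimated correlation). At 10 min 154 responses differed, 44 above and 110 below (989 with the block, 457 up and 532 down), and 67 without WT 0 min library 0, 76 without WT 10 min library 1, 94 without Mut2 0 min library 1, 88 without Mut2 10 min library 0 and 85 without Mut2 10 min library 1. At 20 min 199 differed, 91 above and 108 below (1606 with the block, 792 up and 814 down), and 128 and 131 without WT 0 min library 0 and library 1, 106 without WT 20 min library 1, 111 without Mut2 0 min library 1 and 125 without Mut2 20 min library 0. The compared groups alone gave 0 at 10 min and 9 at 20 min. After rescaling 34.1% of the 20 min differences lay above the wild type instead of 45.7%.

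In Mut3 few responses differed. That of GRE2 was smaller by -2.69 at 10 min (adjusted p = 0.00315) and by -3.03 at 20 min (adjusted p = 0.000821). GRE2 stood higher in Mut3 than in the wild type before salt (605 against 79.3 FPKM) and was not called between them in salt. There it stood at 4120 against 3530 FPKM at 10 min and 5150 against 5580 at 20 min. The response of YML131W was smaller by -1.63 and -1.97, and that of DDR48 by -1.75 at 20 min. HSP12 was called only with the block, at -1.64 at 10 min (adjusted p = 1 without, 0.000605 with) and -1.65 at 20 min (0.704 without, 0.000416 with). ENA1 differed by -1.09 at 10 min (adjusted p = 0.0941 without the block, 0.00523 with) and by -1.32 at 20 min (adjusted p = 0.0203). The second call was lost without WT 0 min library 0 (0.104), Mut3 0 min library 1 (0.115), WT 20 min library 0 (0.067) or library 1 (0.117), or Mut3 20 min library 0 (0.0913) or library 1 (0.0895). The first was gained on rescaling (0.0339) and without Mut2 20 min library 0 (0.0228). RPL22A (4.83) and RPL43A (4.49) lay above at 10 min with the uncertainty given for Mut2, and 3 of the 12 calls belong to features that differ between those sets of libraries. In total 12 responses differed at 10 min, 4 above and 8 below (69 with the block, 21 up and 48 down), and 7 without WT 10 min library 0, 6 without Mut3 0 min library 1 and 7 without Mut3 10 min library 0. At 20 min 19 differed, 5 above and 14 below (237 with the block, 114 up and 123 down), and 6 without Mut3 0 min library 1, 7 without WT 20 min library 1 or Mut3 20 min library 1, 9 without WT 0 min library 0, 10 without Mut3 0 min library 0, WT 20 min library 0 or Mut3 20 min library 0 and 12 without WT 0 min library 1. The compared groups alone gave 0 at 10 min and 6 at 20 min.

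Levels reached in salt were compared directly, a comparison chosen after the data were seen. ENA1, uncertain through its copies, was lower than in the wild type in each mutant: at 10 min 6.64-fold in Mut1 (adjusted p = 1.33e-07), 5.27-fold in Mut2 (adjusted p = 5.57e-07) and 2.1-fold in Mut3 (adjusted p = 0.0018), and at 20 min 7.95-fold, 7.44-fold and 2.46-fold. STL1 was lower at 20 min in Mut1 (2.25-fold, adjusted p = 1.52e-05) and Mut2 (3.35-fold, adjusted p = 2.8e-07), at 10 min in Mut2 (1.53-fold, adjusted p = 0.00179), and not called in Mut3 at either time (adjusted p = 1 and 0.894). At 10 min in Mut1 it was 1.41-fold lower (adjusted p = 0.00665), a call lost without Mut1 10 min library 0 (0.0539) and on rescaling (0.0898). At 20 min GPP2 was 1.85-fold lower in Mut2 (adjusted p = 0.00129) and 1.54-fold lower in Mut1 (adjusted p = 0.0123), the latter call lost without WT 20 min library 1 (0.113) or Mut1 20 min library 0 (0.0999). In Mut2 at 20 min GPD1 was 1.46-fold lower (adjusted p = 0.0226), a call lost on rescaling (0.135) and without WT 20 min library 0 (0.121) or library 1 (0.0959) or Mut2 20 min library 0 (0.102) or library 1 (0.0743). CTT1 was 1.71-fold lower there (adjusted p = 0.0444), a call lost without WT 20 min library 0 (0.0976) or library 1 (0.278) or Mut2 20 min library 0 (0.344). With the block alone, GRE2 was lower at 20 min in Mut1 (adjusted p = 0.000846) and Mut2 (0.000189), GPD1 (0.0142) and CTT1 (0.0341) were lower in Mut1, and ALD3 (0.000172), HSP12 (0.017) and CTT1 (0.0328) were higher in Mut3. OCH1 was higher at 10 min in Mut1 (2.01-fold, adjusted p = 0.00204) and Mut2 (2.06-fold, adjusted p = 0.00186). In Mut3 it was 1.82-fold higher (adjusted p = 0.0269), a call lost without any 1 of the WT or Mut3 libraries at 10 min. With the block the call of OCH1 in Mut3 was kept (adjusted p = 3.29e-06). The log2 difference was 0.89 within library 0 and 0.84 within library 1. At 10 min GPD1, GPP2, GRE2, CTT1, ALD3 and HSP12 were called in none of the mutants without the block. With it GPP2 was lower in Mut1 (adjusted p = 0.00328) and Mut2 (0.0107), CTT1 lower in Mut2 (0.0067), ALD3 higher in Mut1 (0.00371), Mut2 (0.0131) and Mut3 (0.00027), and HSP12 higher in Mut3 (0.0224). In total 874 genes differed at 10 min in Mut1, 428 higher and 446 lower (2730 with the block, 1401 up and 1329 down), 750 in Mut2, 326 higher and 424 lower (2513 with the block, 1282 up and 1231 down), and 110 in Mut3, 67 higher and 43 lower (796 with the block, 428 up and 368 down). At 20 min 461 differed in Mut1, 244 higher and 217 lower (2068 with the block, 1085 up and 983 down), 535 in Mut2, 294 higher and 241 lower (2247 with the block, 1200 up and 1047 down), and 209 in Mut3, 112 higher and 97 lower (1339 with the block, 744 up and 595 down). These totals were not recomputed with single libraries left out. At 10 min 9 of the calls in Mut2 and 7 of those in Mut3 belong to features that differ between the sets of libraries named above. Among them are the largest rises that the naming rule took in Mut3, RPL22A (27-fold), RPL43A (19.7-fold), RPL39 (14.3-fold) and RPL36B (11-fold), which are therefore uncertain.

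**Figure D3:**
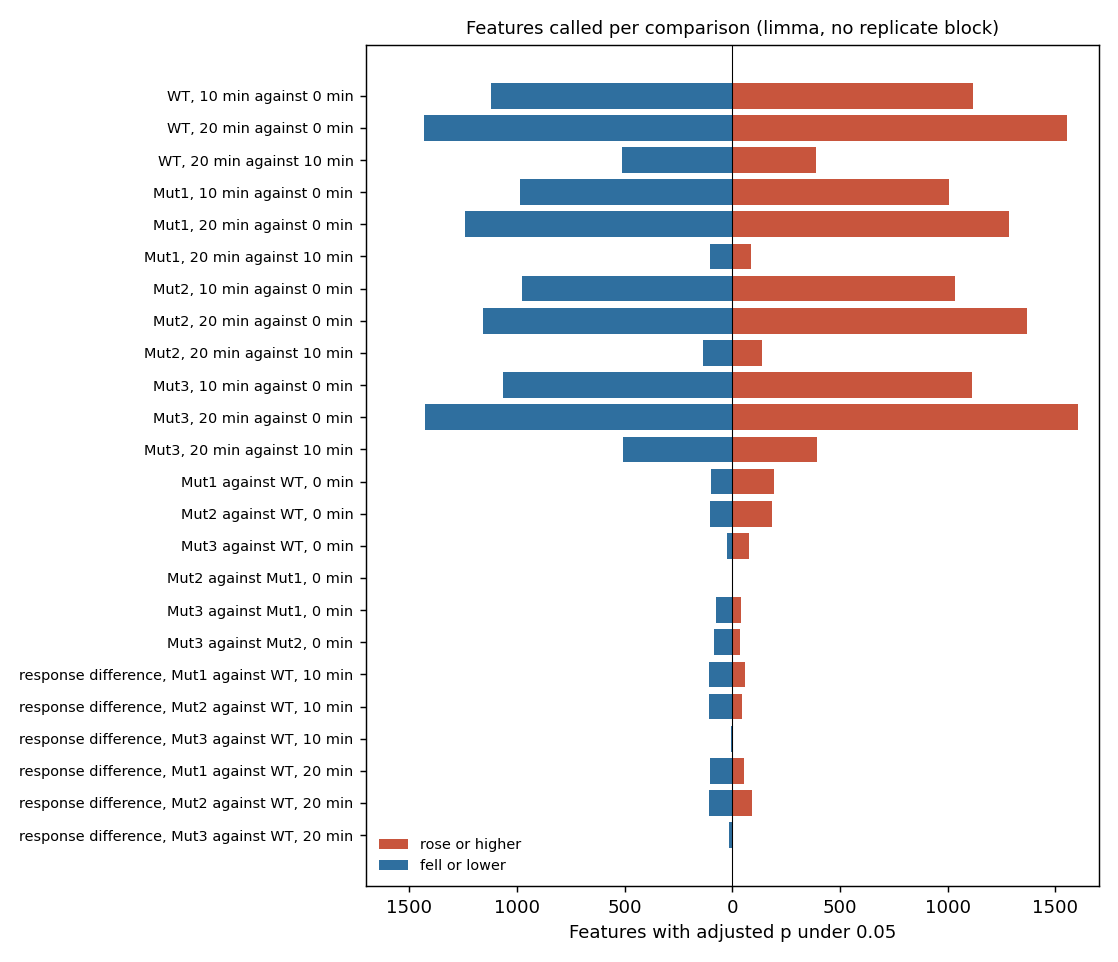
Number of genes with adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis), split into those above and below the reference group. Salt changed 2239 genes at 10 min in the wild type, and Mut1, Mut2 and Mut3 differed from it in 294, 287 and 103 genes before salt.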

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

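All explanations weighed in this part were tested only after the results were seen, whereas the response differences themselves were planned. The results below were singled out because the salt response of a mutant differed from that of the wild type in a test of the difference itself. At 10 min 165 responses differed in Mut1, 154 in Mut2 and 12 in Mut3. At 20 min the counts were 159, 199 and 19. In Mut1 the log2 differences at 10 min were -1.23 for STL1, -2.12 for GPD1, -2.86 for ENA1, -2.92 for GRE2 and -4.73 for HSP12. At 20 min they were -1.91, -2.30, -3.12, -3.37 and -4.86 for the same genes. In Mut2 they were -1.26, -1.91, -2.36, -3.11 and -4.16 at 10 min and -2.39, -2.37, -2.85, -3.66 and -4.36 at 20 min. In Mut3 GRE2 differed by -2.69 at 10 min and by -3.03 at 20 min, and ENA1 by -1.32 at 20 min.

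The difference in response is by construction the difference in salt minus that at 0 min, so a smaller response must come from a higher level before salt, a lower level in salt or both, and the counts show only how the genes divide. Of the 94 genes that salt raised in the wild type and whose response was smaller in Mut1 at 10 min, 50 were called higher than in the wild type at 0 min and 54 lower at 10 min, 39 and 43 of them in that part alone. HSP12 stood at 1610 FPKM in Mut1 against 56.7 in the wild type at 0 min, and at 23300 against 23000 at 10 min. ENA1 went the other way, with 3.57 against 3.2 at 0 min and 18.8 against 131 at 10 min. Scaling of the columns is argued against as the whole cause, since 218 responses differed after median-ratio rescaling. Both parts thus occur among the called genes, but no cause of either was tested, and the wild type libraries at 0 min enter the response as well as the comparison at 0 min.

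LEU2 rose in salt in all 4 strains, by a log2 value of 1.41 at 10 min in the wild type. A rise of LEU2 reads as a whole in proportion to STL1, through the reporter under the STL1 promoter at that locus, is argued against. At 20 min the response of STL1 was smaller in Mut2 by -2.39, while the lower 95% limit for LEU2 was -0.58. That value cannot speak to reporter reads added to those of LEU2 itself, since LEU2 rose by only 1.41. Added reads in proportion to STL1, as the source of the whole rise, are argued against by the levels at 20 min. LEU2 went from 353 ± 30.2 to 994 ± 44.3 FPKM in the wild type, with STL1 at 3050. It went from 298 ± 36.1 to 1130 ± 181 in Mut1, with STL1 at 1360. In Mut2 it went from 316 ± 57 to 860 ± 76.9, with STL1 at 915. Reporter reads as a part of the rise stay open. Joint regulation with the whole leucine and branched-chain pathway is argued against by 7 other genes, whose median change was -0.39 with 4 down. LEU1 alone of these rose, 2.22-fold (1.15, limma adjusted p = 2e-05), so regulation shared by LEU1 and LEU2 stays open. Scaling is argued against too, since LEU2 still rose by 1.37 after rescaling (limma adjusted p = 1.04e-07). Other regulation of the marked locus stays open and was not tested.

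RPL22A, RPL43A, RPL36B and RPL39 differ between 2 sets of 12 libraries with no overlap. The first set holds all libraries at 0 min and those of the wild type and Mut1 at 10 min, and the second the other libraries. RPL22A lay at 4.44 to 17.6 FPKM in the first and 80.1 to 238 in the second. A search by size alone, without a test, gave 56 features with a shift over 1 in both 10 min comparisons across the sets, and 6 of these have no overlap between the sets. RPL22A, RPL43A, RPL36B and RPL39 have no near-identical copy by the blastn rule. Reads moving between the copies of RPL22A, RPL43A and RPL36B are argued against, since the other copies differed by a median of -0.01 where -0.61 would be needed. The SE was 0.12 over 6 comparisons of 3 pairs, which share libraries and are not independent. RPL39 was not in that test. A difference in how reads were assigned to features stays open. RNA genes, unmatched and overlapping features make up 51.8% of the 56, above the 12.4% of the other tested features (Fisher exact p = 1.72e-12), but also 65.9% of the 41 features of the same size with opposite signs (Fisher exact p = 0.213). A search by size picks such features under either sign, so their share decides nothing. A later salt response in the wild type and Mut1 cannot be told apart from a difference in read assignment. The median change of RPL22A, RPL43A, RPL36B and RPL39 between 10 and 20 min in the wild type was 3.54. Within each strain the sets divide the times, before 20 min in the wild type and Mut1 and before 10 min in Mut2 and Mut3. Across strains they do not coincide with time, since 10 min lies in both. The first set is also the first 12 samples in the order of the labels, which was not tested as a cause.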

How the results depend on the processing

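The block with rescaling, protein-coding genes alone and the omission of library 0 of Mut2 at 20 min from every comparison were chosen after seeing the data, and the other alternatives were planned. With a pseudocount of 0.1 FPKM, no filter, median-ratio rescaling or protein-coding genes alone, each of the 27 counts and shifts kept its size to within 1.5 times, and the shifts kept their direction. The balance of rises and falls within some counts turned on rescaling. The share that rose went from 46.1 to 59.7% for Mut1 at 20 against 10 min, and from 54.1 to 49.9% for Mut2 at 20 against 0 min. Read depth could not be varied, since counts were not used here.

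Counts are given in a fixed order: for a strain 10 against 0, 20 against 0 and 20 against 10 min, before salt Mut1, Mut2 and Mut3 against the wild type, then Mut2 against Mut1, Mut3 against Mut1 and Mut3 against Mut2, and for the responses Mut1, Mut2 and Mut3. With the library number as a block the time counts were 3918, 4494 and 2658 in the wild type and 3697, 4041 and 1290 in Mut1. They were 3741, 4109 and 1803 in Mut2 and 3851, 4478 and 2693 in Mut3. Before salt they were 1148, 1326, 503, 1, 563 and 644. The response counts were 1042, 989 and 69 at 10 min and 984, 1606 and 237 at 20 min. In total 23 of 27 rose by more than 1.5 times. Every group holds library 0 and library 1, so the block leaves each log2 change and median shift as it was. A reversal of a named gene or shift was therefore not possible, and the block reversed no list. Between 10 and 20 min, however, more called genes fell than rose without the block, and more rose than fell with it. The share that rose went from 43.1 to 54.5% in the wild type, 46.1 to 50.5% in Mut1, 49.6 to 51.8% in Mut2 and 43.6 to 57.2% in Mut3. The pairing of libraries by number across groups thus takes up part of the spread that the fit without a block counts as noise.

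With the block within each strain the time counts were 3903, 4494 and 2662 in the wild type and 3698, 4057 and 1326 in Mut1, then 3712, 4117 and 1784 in Mut2 and 3845, 4465 and 2696 in Mut3. The response counts were 1034, 995 and 76 at 10 min and 998, 1615 and 256 at 20 min. It was not planned for the comparisons before salt and not run there. The cause was not tested.

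With the block and rescaling together they were 4060, 4570 and 2748 in the wild type and 3813, 4146 and 1482 in Mut1, then 3829, 4168 and 1962 in Mut2 and 3949, 4522 and 2767 in Mut3. Before salt they were 1311, 1507, 620, 14, 652 and 746. The response counts were 1258, 1181 and 98 at 10 min and 1185, 1782 and 291 at 20 min. The cause was not tested.

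A fit on the compared groups alone has fewer samples and lowered 22 of the 27 by more than 1.5 times. The time counts were 868, 1908 and 0 in the wild type and 1014, 1393 and 5 in Mut1, then 431, 782 and 0 in Mut2 and 1088, 2164 and 0 in Mut3. Before salt they were 0, 0, 0, 0, 6 and 2. The response counts were 7, 0 and 0 at 10 min and 23, 9 and 6 at 20 min.

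Leaving out a library leaves a lone sample in its group, which is assumed to vary like the other groups. The time counts then ran over 1707 to 2284, 2282 to 3036 and 430 to 920 in the wild type. They ran over 1412 to 2012, 1909 to 2559 and 32 to 196 in Mut1. They ran over 1412 to 2040, 2018 to 2266 and 34 to 261 in Mut2. They ran over 1588 to 2213, 2451 to 3035 and 406 to 926 in Mut3. Before salt they ran over 176 to 280, 169 to 290, 73 to 106, 0 to 2, 50 to 113 and 35 to 121. The response counts ran over 79 to 148, 67 to 148 and 6 to 11 at 10 min and 88 to 154, 106 to 291 and 6 to 22 at 20 min.

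The shifts of salt-induced genes at 0 min, with medians of 0.26, 0.20 and 0.21, lost their calls with an estimated correlation, which enters only the p (0.134, 0.185 and 0.114). Leaving out a library moved the medians over 0.13 to 0.41 in Mut1, 0 to 0.43 in Mut2 and 0.05 to 0.35 in Mut3. The cause was not tested.

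The direction that camera gave to 2 lists turned in 14 cases when single libraries were left out, which leaves the library numbers unbalanced in the same way. Camera weighs all members, so the median need not change sign with it, and equal values are printed once. The median of the ribosomal protein list went from -0.12 to 0.04 (range -0.31 to 0.04) for Mut1 against the wild type at 0 min, -0.11 to 0.07 and 0.10 (range -0.32 to 0.10) for Mut3 against the wild type at 0 min, 0.11 to -0.03 (range -0.03 to 0.31) for Mut2 against Mut1. It went from -0.09 to -0.01 and 0.11 (range -0.30 to 0.11) for Mut3 against Mut2, -0.15 to 0.01, 0.04 and 0.07 (range -0.36 to 0.07) for the Mut3 response at 10 min, -0.16 to 0.04 and 0.07 (range -0.35 to 0.07) for the Mut3 response at 20 min. That of ribosome biogenesis in the Mut2 response at 10 min went from -0.23 to 0.02 (range -0.53 to 0.02). Among the named genes and lists, 14276 of 17352 values kept their call when a library was left out, 2125 lost it, 163 gained it, 774 moved and 14 turned. On rescaling 2779 of 3122 kept it, 247 lost it and 60 gained it, and with the block 2888 kept it, 20 lost it (gene lists in each case) and 186 gained it.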
